A study of Homo sapiens with 75 samples.

How the data were processed

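Gene expression was measured by RNA sequencing in 75 libraries of human acute myeloid leukaemia cells. Of these, 72 came from 8 derivatives of the MOLM14 line that had been selected for resistance to gilteritinib, an inhibitor of the FLT3 receptor tyrosine kinase, and 3 came from the parental MOLM14 line. Per the labels' protocols, total RNA was isolated with a miRNeasy kit and sequencing libraries were made from polyadenylated RNA with a TruSeq stranded mRNA kit. Antisense oligonucleotides (ASO), short modified nucleic acids that direct degradation of a matching RNA, were given at 5 µM every other day over 96 h, and gilteritinib was then given at 100 nM. The resistant cultures were kept in 100 nM gilteritinib, per the labels' protocols; whether the drug was withdrawn during the ASO treatment is not given in the sources used here.

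The deposited files hold, per transcript, the estimated count of read pairs and the effective transcript length that Salmon writes, per the file headers. The estimated counts were not normalized, and each file holds 1 library. Per the submitters' processing notes, bcl2fastq, kallisto 0.46.2, Salmon, edgeR and limma were used with build GRCh37; the order and role of these tools and the Salmon version are not given in the sources used here. Each file listed 228297 transcripts, of which 205269 matched GENCODE 29 by identifier; 194135 matched with the same version and 192575 of those had the same length. The HGNC table of that release gave symbols to 17409 more transcripts, and 5619 had none. The transcript set thus matched an annotation of build GRCh38 rather than GRCh37, and positions below are those of GRCh38. Estimated counts were summed over the transcripts of each of 56065 gene symbols and rounded to whole numbers. Transcripts without a symbol held between 1.01% and 1.32% of a library's reads and were left out of library sizes and tests. Because Salmon divides reads among similar transcripts, values of near-identical genes, such as multi-copy microRNA genes, members of the GOLGA8 family, HSPA1A with HSPA1B, and pseudogenes, are uncertain. The strand setting of the counting is not given in the sources used here, so overlapping antisense genes are uncertain too.

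Library totals had a median of 27.6 M reads (megareads) and ranged from 2.33 to 56.2 M. Both libraries under 17.7 M reads were control ASO libraries at 0 h, from 12L with 2.33 M and 8L with 2.79 M reads. In pairs of libraries of a group, the lowest chi-square per gene was 10.9 over 252 pairs, so no library was counted as a copy of another. The group of every library was taken from its title. The labels also number the replicates by line, 5 to 12, and 1 line received every treatment at every time, so libraries of equal number come from the same line. As a check, deviations from the group means were correlated: the median within a line was 0.376 over 288 pairs with a lowest value of 0.001, the median between lines was -0.170, or 0.215 between lines of the same genotype, and 68 of 72 libraries lay closest to a library of their own line. The 8 lines descend from 1 parental line, and no line had a second library of the same treatment and time. With the line as a block, p-values of the main fit measure the spread left within lines. That spread is shared over all 72 libraries and is not taken from the compared groups alone. For untreated G12S against G12D lines they measure the spread between the lines of a genotype.

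The main test was edgeR's quasi-likelihood F test with TMM normalization, filterByExpr and Benjamini-Hochberg adjustment, with calls at an adjusted p under 0.05. It was fitted to all 72 resistant libraries with the line as a block, over 28463 genes. Differences between genotypes used genotype by treatment groups, and the comparison of untreated G12S with G12D lines used its 8 libraries alone, over 25573 genes. Adjusted p-values without another name below come from these fits. CPM are counts scaled to library size with TMM factors, computed here. Differences of lines are on the log2 CPM scale with a prior count of 2. Because 1 MOLM14 library existed per time, parental values carry no replicate error, and gene lists in them were placed among 10000 random lists of the same size matched on mean expression.

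Gene lists, tests, samples and covariates were fixed before the data were examined. The 28 lists covered RAS and RAF pathway members, RAS/MAPK output, immediate-early genes, mature monocyte markers, primitive progenitor markers, granulocyte-monocyte progenitor and granule genes, MHC class II genes, STAT5 and cytokine feedback targets, MYC and ribosome biogenesis, S phase, G2/M phase, survival and death members of the BCL2 family, p53 targets, the type I interferon response, NF-kB and inflammatory cytokine genes, cholesterol synthesis, the ATF4 and amino acid response, the unfolded protein response, glycolysis and hypoxia, lysosome genes, the heat shock response, mitochondrially encoded transcripts as a sign of RNA quality, growth factor receptors and ligands, and markers of erythroid, megakaryocytic, lymphoid and fibroblast cells. Each list was tested with camera on voom values with a preset correlation of 0.01, adjusted over the 28 lists of a comparison, and again with an estimated correlation. Of 476 list and comparison pairs, 197 passed with the preset correlation and 17 with the estimated one. Beside it, the mean difference of the list in each line was tested with an exact two-sided sign-flip test, whose smallest p over 8 lines is 0.00781, or an exact two-sided permutation of 4 against 4 lines, whose smallest p is 0.0286.

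Genes were named by a rule set at the same time. It took NRAS, HRAS, FLT3, DUSP6, SPRY4, CD14, MPO and MYC, and per comparison the 6 largest rises and 6 largest falls among genes with an adjusted p under 0.05, a mean CPM of at least 5 and the same sign in at least 7 of 8 lines. For genotype comparisons the lines' values had not to overlap. From each described list it took up to 4 members of lowest adjusted p and the largest opposite change. Of the tested genes, 58 linked to sex chromosomes stayed in the tests but were left out of the tables, and the next genes took their places. Some genes that the rule also took are not reported here.

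Alternatives set beforehand were no filter on low counts, a mean CPM of at least 10, RLE size factors, DESeq2, limma-voom, offsets from effective transcript lengths, no replicate block, only the groups compared, no libraries under 0.5 of the median total, no ASO as the reference, Spearman correlation, a prior count of 5 and leaving out each line. Further alternatives were added after the data had been seen. They left out the 4 h pair of 5L, alone or with the shallow libraries. They also compared arms within a genotype, in the fit to all lines, with all libraries or without both kinds. Others used no ASO as the reference without these libraries or without the block, and similarity without 8L and 12L or without 5L, 8L and 12L. The steps were tested on simulated counts in which 200 genes were changed. For NRAS ASO against control ASO at 0 h, over 28191 genes, 52.2% of 1.5-fold, 77.6% of 2-fold and 98.5% of 4-fold changes were recovered, with 10 false among 162 calls. For the genotype comparison at 24 h, over 28179 genes, these shares were 10.4%, 44.8% and 86.4%, with 1 false among 95 calls, and for untreated G12S against G12D lines, over 25894 genes, 31.8%, 87.7% and 100.0%, with 7 false among 151 calls. Of the 28 lists, 0 were called with no simulated change. The simulated genes varied independently of each other, so this does not show how the preset correlation performs where genes of a list vary together. For the untreated lines the simulation averaged the line means and gave all genes a common dispersion. No simulated library had the altered composition of the shallow libraries or exchanged labels. The rates of recovery and of false calls therefore need not hold for the real data. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, the R package data.table at version 1.17.8, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.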

Results

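The series asked whether lowering NRAS in leukaemia cells that had become resistant to a FLT3 inhibitor altered their cell state and their response to the drug. MOLM14 is an acute myeloid leukaemia line that grows on signals from mutant FLT3. From it came 8 gilteritinib-resistant lines, 5L, 6L, 7L and 8L labelled as carrying NRAS G12S and 9L, 10L, 11L and 12L labelled as carrying NRAS G12D, both activating changes of this small GTPase. Each resistant line was cultured in 3 arms, with media alone (no ASO), with 5 µM of a non-targeting control ASO or with 5 µM of an ASO against NRAS, and each arm was sampled at 0, 4 and 24 h of 100 nM gilteritinib. This gave 9 groups of 8 libraries, 1 per line, and MOLM14 without ASO gave 1 library at each time. Library totals were between 17.7 and 56.2 M reads (megareads) except for the control ASO libraries at 0 h of 12L, with 2.33 M, and 8L, with 2.79 M.

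NRAS lies on chromosome 1 at 114704469 to 114716894 on the minus strand (ENSG00000213281), HRAS on chromosome 11 at 532242 to 537287 and FLT3 on chromosome 13 at 28003274 to 28100592 (ENSG00000122025), all on GRCh38. The part of the NRAS transcript that the ASO binds is not given in the sources used here. NRAS stood at 119 ± 21.4 CPM (SD, n = 8) without ASO at 0 h, 128 ± 23.5 at 4 h and 110 ± 23.1 at 24 h. The NRAS ASO lowered it to 42.0 ± 22.8, 54.3 ± 37.0 and 35.3 ± 15.8 CPM, against 94.7 ± 48.0, 122 ± 51.8 and 112 ± 24.6 CPM with the control ASO. In G12S lines the NRAS ASO libraries held 20.9 ± 2.16 CPM at 0 h and 21.8 ± 2.92 at 24 h (n = 4), and in G12D lines 63.0 ± 5.32 and 48.7 ± 9.42 CPM (n = 4). NRAS changed by -1.24 log2 units at 0 h (SE 0.33, adjusted p = 0.0207), by -1.19 at 4 h (SE 0.33, adjusted p = 0.102) and by -1.71 at 24 h (SE 0.33, adjusted p = 6.41e-05).

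In 4 libraries NRAS went against its label. At 4 h the library labelled control ASO of 5L held 19.5 CPM and the library labelled NRAS ASO of 5L held 133 CPM. The control ASO libraries of 8L and 12L at 0 h, which were the shallow ones, held 25.6 and 14 CPM. In the shallow libraries the 10 most abundant genes took 16.4% (8L) and 16.6% (12L) of the reads, against 6.40% to 8.69% in the other 6 control ASO libraries at 0 h. Their mitochondrial share was 0.636% and 0.546%, against 1.81% to 2.78% in those 6. Without these 4 libraries the NRAS change was -1.61 log2 units at 0 h (SE 0.24, adjusted p = 6.96e-06) and -1.71 at 4 h (adjusted p = 9.64e-07). The 5L pair was doubted because of its NRAS values, so the NRAS test without it is no independent evidence of the knockdown. The main counts of genes in comparisons fitted with these 4 libraries are therefore also given without them, an alternative chosen after the data had been seen.

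**Figure D1:**
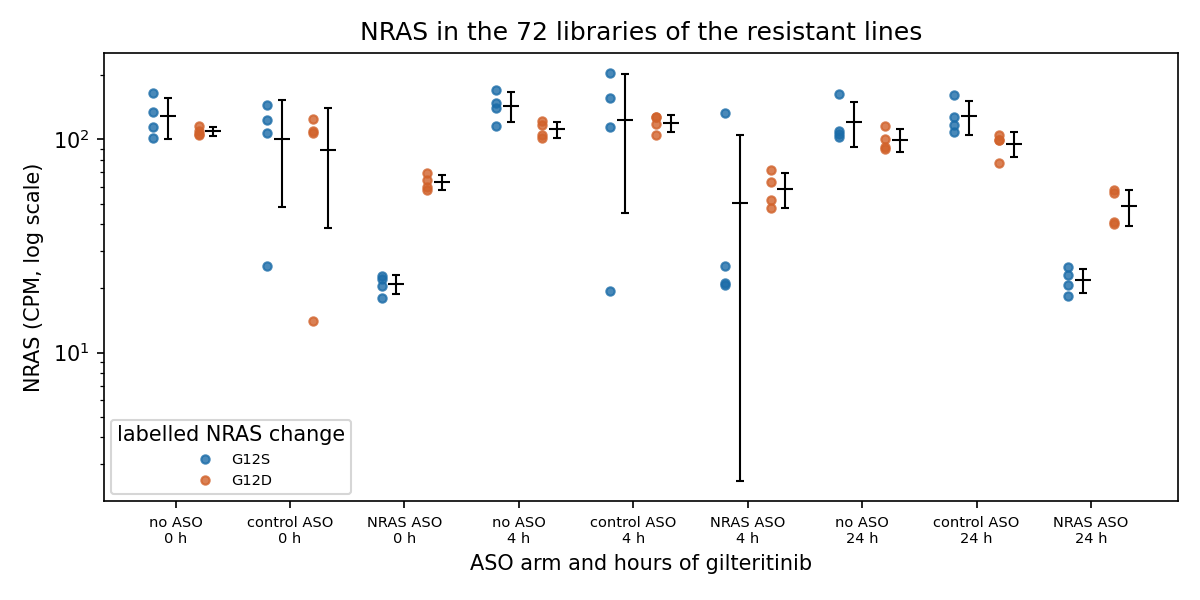
NRAS in CPM on a log axis, 1 point per library, by ASO arm and hours of gilteritinib. Bars give the mean and SD over the 4 lines of each genotype, and colours mark NRAS G12S and G12D lines. The 5L library labelled control ASO at 4 h lies at 19.5 CPM among the knockdown values, and the 5L library labelled NRAS ASO at 133 CPM lies among the controls.

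The resistant cultures were kept in gilteritinib, and whether they were free of it at 0 h is not given in the sources used here. At 0 h the largest falls with NRAS ASO included FCER2, the low-affinity IgE receptor, at -1.90 log2 units (SE 0.24; 19.2 ± 18.6 against 76.7 ± 73.9 CPM, n = 8) and the lectin gene CD209 at -1.85 (SE 0.27). Versican (VCAN), a matrix proteoglycan of monocytes, stood at -1.78 (SE 0.30), the heat shock gene HSPA6 at -1.74 (SE 0.38), collagen VII (COL7A1) at -1.65 (SE 0.21) and osteopontin (SPP1) at -1.53 (SE 0.28). Among the largest rises were MFAP4 at 1.02 log2 units (SE 0.17), GOLGA8O at 0.89 (SE 0.21), the granule protease CTSG at 0.84 (SE 0.15), NAPSB at 0.78 (SE 0.14) and VAT1L at 0.77 (SE 0.13). FLT3 rose by 0.64 (SE 0.16, adjusted p = 0.0106), and by 0.32 (adjusted p = 0.00261) without the 4 libraries. DUSP6, a phosphatase that limits ERK, stood at -0.74 (adjusted p = 0.0640; -0.94 and adjusted p = 0.00796 without them). SPRY4 stood at -0.48 (adjusted p = 0.392), MYC at 0.65 (adjusted p = 0.0562), MPO at 0.43 (adjusted p = 0.0523), CD14 at -0.40 (adjusted p = 0.290) and HRAS at -0.06 (adjusted p = 0.817).

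Of 21 immediate-early genes 7 fell at 0 h (9 when adjusted over the list alone), among them the transcription factors EGR3 (-1.44) and NR4A1 (-0.67) and the survival factor IER3 (-0.81). Of 21 NF-kB and cytokine genes 7 fell (11 adjusted over the list alone), with IL1B at -1.77 and NFKB2 at -0.82. Of 33 mature monocyte markers 7 fell (9 adjusted over the list alone), with ITGAX at -0.82 and CSF1R at -0.52. RAS/MAPK output had 3 of 16 members lower (6 adjusted over the list alone), PHLDA1 at -1.37, PLAUR at -0.77 and DUSP4 at -0.85. Camera called these 4 lists down (adjusted p between 1.35e-12 for immediate-early genes and 6.39e-05 for RAS/MAPK output), and the calls were lost with an estimated correlation (adjusted p = 0.123, 0.123, 0.284 and 0.388 with an estimated correlation, in the order above). Without the 4 libraries 9, 8, 8 and 5 members fell, and the 4 calls held with an estimated correlation (adjusted p = 0.0196, 0.000287, 0.0126 and 0.0196). Of 16 primitive progenitor markers 5 rose and 3 fell, KIT, the stem cell factor receptor, by 1.35 and MECOM at -2.28 (-0.27, adjusted p = 0.900, without the 4 libraries). MYC and ribosome biogenesis had 2 of 25 members higher (8 adjusted over the list alone; adjusted p = 0.506 with an estimated correlation). Mitochondrially encoded transcripts had 0 of 13 higher over all genes and 10 when adjusted over the list alone (adjusted p = 0.284 with an estimated correlation), and 0 either way without the 4 libraries, of which the shallow ones had the low mitochondrial share. Among lymphoid markers TRAC (-1.02) and CD3D (-1.53) fell.

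At 0 h edgeR's quasi-likelihood test called 1565 of 28463 genes at an adjusted p under 0.05, 581 higher and 984 lower with NRAS ASO, and 839 genes (192 higher, 647 lower) without the 4 libraries. A fit to only the groups compared called 2 genes, both lower, with 1239 at an unadjusted p under 0.05. With limma-voom the split was 1111 higher and 573 lower. Against no ASO in place of the control ASO 221 genes passed, and 735 without the 4 libraries. Within the G12D lines, of which 12L held a shallow library, 2 passed, and 95 without the 4 libraries. Within the G12S lines 1100 passed, and 1958 without the 4 libraries. Counts within a genotype, here and below, come from the fit to all lines, whose spread the genotypes share.

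At 4 h of gilteritinib the genes lower with NRAS ASO again included VCAN at -1.95 log2 units (SE 0.30; 2.64 ± 3.12 against 12.3 ± 15.7 CPM, n = 8), SPP1 at -1.72 (SE 0.28), CD209 at -1.32 (SE 0.27) and FCER2 at -1.30 (SE 0.24), beside the cytokine TNF at -1.40 (SE 0.30), the chemokine CXCL10 at -1.23 (SE 0.29) and CD14, the monocyte co-receptor for endotoxin, at -1.02 (SE 0.23, adjusted p = 0.0258). The rises were the growth factor receptor FGFR3 at 1.03 (SE 0.25), the kinase MAP2K6 at 0.70 (SE 0.15), MYO18A at 0.52, GOLGA8J at 0.50 and SKIDA1 at 0.48. These differences include the 5L libraries labelled control ASO and NRAS ASO, whose NRAS levels went against the labels. Without the 4 libraries DUSP6 fell by 1.10 (adjusted p = 0.000621), the RAS feedback inhibitor SPRY4 by 1.52 (adjusted p = 0.000487) and CD14 by 1.22 (adjusted p = 0.000292), MPO rose by 0.45 (adjusted p = 0.00793) and FLT3 by 0.22 (adjusted p = 0.0236). With all libraries DUSP6 stood at -0.82 (adjusted p = 0.177), SPRY4 at -1.10 (adjusted p = 0.230), MPO at 0.37 (adjusted p = 0.330), FLT3 at 0.16 (adjusted p = 0.945), MYC at -0.20 (adjusted p = 0.970) and HRAS at -0.05 (adjusted p = 1.00).

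Of 21 NF-kB and cytokine genes 3 fell at 4 h (12 adjusted over the list alone), with TNFAIP3 at -0.85 and CCL5 at -0.55, and of 33 mature monocyte markers 3 fell (7 adjusted over the list alone), VCAN and CD14 among them. RAS/MAPK output had 0 of 16 members past the threshold over all genes and 13 lower when adjusted over the list alone, DUSP4 at -0.84 (adjusted p = 0.0603), CCND1 at -1.21 (adjusted p = 0.0755) and PLAUR at -0.60 (adjusted p = 0.0585) among them. These 3 lists were lower by camera and held with an estimated correlation (adjusted p = 0.00158, 0.00967 and 0.00967). Lymphoid markers were lower too (1 fell, CD3D at -1.79; adjusted p = 0.0415 with an estimated correlation). Glycolysis and hypoxia genes had 1 of 24 lower, SLC2A3 at -0.79 (8 adjusted over the list alone; adjusted p = 0.110 with an estimated correlation). Without the 4 libraries 12 NF-kB genes, 10 monocyte markers, 13 RAS/MAPK genes and 12 glycolysis genes fell (adjusted p = 0.000384, 0.00685, 0.00167 and 0.0295 with an estimated correlation). By edgeR's quasi-likelihood test 68 genes passed, 10 higher and 58 lower, and 2303 (846 higher, 1457 lower) without the 4 libraries. Leaving out the 5L pair alone gave 794 genes, and DESeq2 with all libraries gave 98 higher and 142 lower. A fit to only the groups compared called 0 genes, with 3498 at an unadjusted p under 0.05.

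After 24 h of gilteritinib more genes differed between the arms than at 0 or 4 h, and all 25 genes of each of the lists for MYC and ribosome biogenesis, S phase and G2/M were lower with NRAS ASO (adjusted p = 0.100, 0.100 and 0.156 with an estimated correlation). MYC, a driver of growth, fell by 0.99 log2 units (SE 0.22, adjusted p = 0.000351), from 399 ± 78.4 to 208 ± 104 CPM (n = 8). SPRY4 fell by 1.58 (SE 0.39, adjusted p = 0.00119), from 11.9 ± 1.92 to 4.76 ± 4.22 CPM, and CD14 by 1.56 (SE 0.31, adjusted p = 7.26e-05), from 0.467 ± 0.425 to 0.149 ± 0.117 CPM. FCER2 fell by 2.77 (SE 0.27) and HRAS by 0.37 (SE 0.12, adjusted p = 0.0173). The largest rises were KIT at 1.79 (SE 0.30), the actin-binding gene SYNPO at 1.77 (SE 0.25), BMF, a death member of the BCL2 family, at 1.74 (SE 0.23), the hypoxia factor EPAS1 at 1.70 (SE 0.25), the pseudogene BTBD6P1 at 1.66 (SE 0.25) and PRUNE2 at 1.49 (SE 0.20). The multi-copy microRNA genes MIR3687-1 and MIR3687-2 (both -4.05), MIR3648-1 and MIR3648-2 (both -3.05) and MIR663B (-2.79) also fell, with uncertain counts. DUSP6 stood at -0.53 (adjusted p = 0.113), FLT3 at 0.21 (adjusted p = 0.317) and MPO at -0.32 (adjusted p = 0.0813).

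All 25 genes of MYC and ribosome biogenesis, all 25 of S phase and all 25 of G2/M fell at 24 h, over all genes and when adjusted over the list alone. Examples were the spermidine synthase SRM (-1.21) and RRP12 (-0.80), the cell cycle factors CCNE2 (-1.31) and E2F1 (-1.24), and CCNA2 (-1.09) and CDC20 (-0.91). Each list was lower in 8 of 8 lines (exact sign-flip p = 0.00781, adjusted p = 0.0137). Of 16 RAS/MAPK output genes 12 fell and 1 rose (14 and 1 adjusted over the list alone), with ETV4 at -1.49, ETV5 at -1.42, CCND1 at -1.98, SPRY1 at -1.23 and EPHA4 at 0.35. Of the unfolded protein response 16 of 18 fell (HSPA5 at -0.95, SDF2L1 at -1.37), and of cholesterol synthesis 15 of 21 (17 adjusted over the list alone; DHCR7 at -0.90, SQLE at -0.91). Of the ATF4 response 14 of 22 fell and 1 rose (SLC7A5 at -1.21, PSAT1 at -1.02), of glycolysis and hypoxia 12 of 24 fell (PKM at -0.80, PGAM1 at -0.85) and of heat shock 9 of 14 (11 adjusted over the list alone; HSPA8 at -1.18). Camera called these lists down, adjusted p between 1.38e-21 and 3.39e-07. All of the calls were lost with an estimated correlation, at adjusted p = 0.100 for MYC, S phase, ATF4 and the unfolded protein response, 0.120 for cholesterol and heat shock, 0.156 for G2/M, 0.157 for RAS/MAPK and 0.184 for glycolysis.

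**Figure D2:**
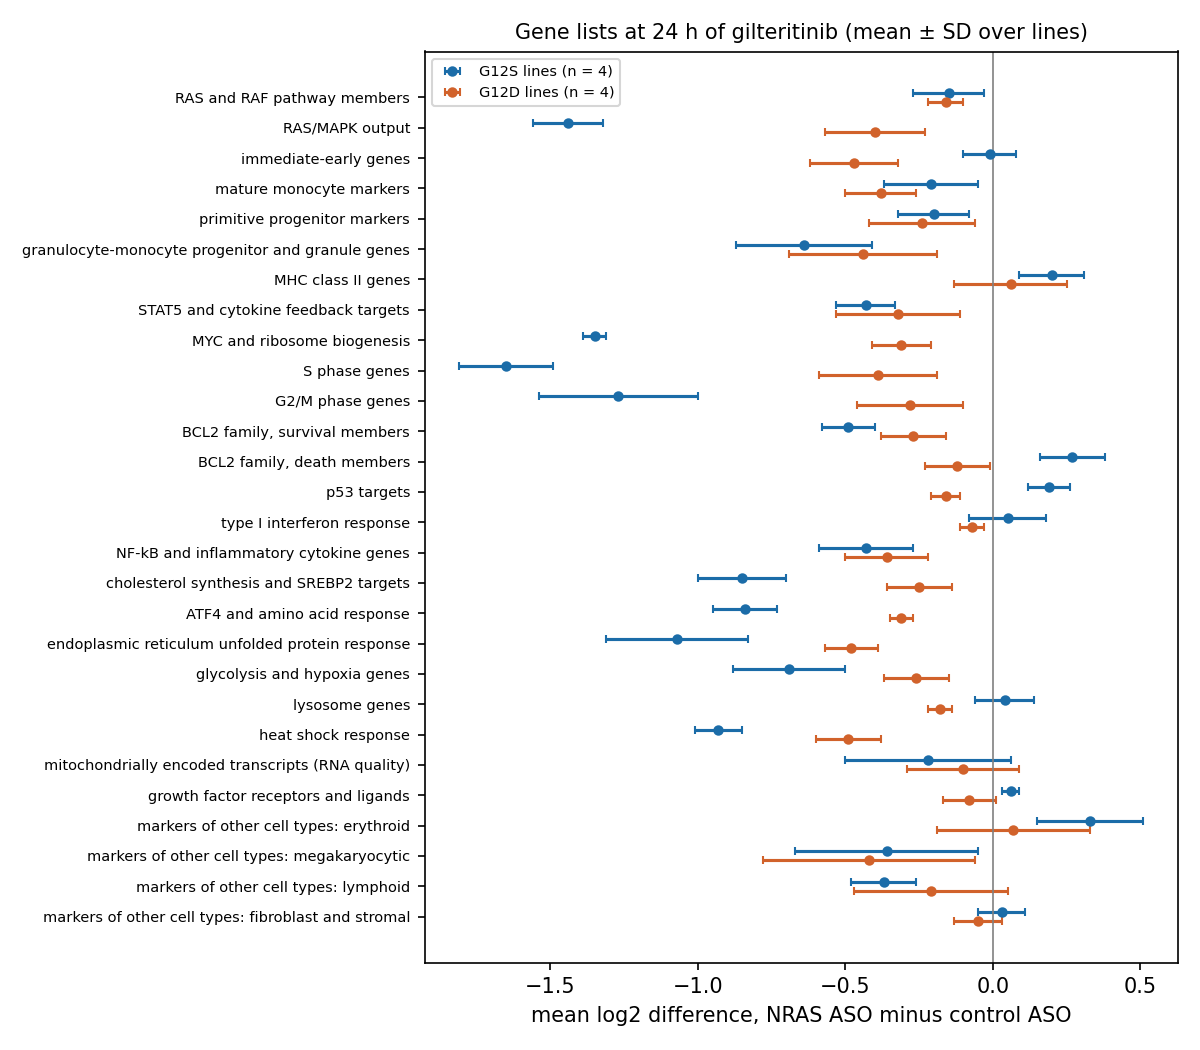
Mean log2 difference of NRAS ASO from control ASO at 24 h of gilteritinib for the 28 gene lists, with the mean and SD over the 4 G12S and the 4 G12D lines. MYC and ribosome biogenesis lay at -1.35 in G12S and -0.31 in G12D lines, and S phase genes at -1.65 and -0.39.

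Myeloid lists were mixed at 24 h. Of 33 mature monocyte markers 10 fell and 3 rose (11 and 3 adjusted over the list alone): VCAN at -2.12 and the calprotectin subunit S100A9 at -1.30 were lower, while the receptors CSF1R at 0.56 and CD36 at 0.87 were higher. Of 16 granule genes 9 fell and 2 rose (11 and 2 adjusted over the list alone), with CEBPE at -1.17, PRTN3 at -1.13 and CTSG at 0.49, and of 16 progenitor markers 4 fell and 3 rose, with GATA2 at -1.63 against KIT. With an estimated correlation adjusted p was 0.446, 0.326 and 0.759. Among survival members of the BCL2 family BCL2A1 (-1.28) and BCL2 (-0.44) fell and BCL2L2 (0.18) rose, and among 10 death members BMF rose while 2 fell, BID (-0.51) one of them. STAT5 targets had 7 of 15 lower (CCND2 at -0.88; adjusted p = 0.330 with an estimated correlation), and NF-kB genes 9 of 21 lower and 1 higher (TNF at -1.84, CCL5 at -0.84; adjusted p = 0.446 with an estimated correlation). RAS and RAF pathway members had 6 of 25 lower and 1 higher (adjusted p = 0.545 with an estimated correlation; the list median of -0.13 became 0.02 with length offsets). Counts were 1 higher and 3 lower for immediate-early genes, 2 and 0 for MHC class II, 3 and 2 for p53 targets and 4 and 3 for interferon genes (STAT2 at 0.60, CXCL10 at -2.27). They were 1 and 4 for lysosome genes, 0 and 0 for mitochondrial transcripts, 6 and 3 for receptors and ligands, 1 and 1 for erythroid, megakaryocytic and fibroblast markers each, and 1 and 3 for lymphoid markers (TRAC at -1.44). Median and mean differed in sign for interferon genes (0.11 and -0.02), megakaryocytic markers (0.03 and -0.43) and lymphoid markers (0.03 and -0.46).

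By edgeR's quasi-likelihood test 7823 genes passed at 24 h, 3633 higher and 4190 lower, and 12021 (6046 higher, 5975 lower) without the 4 libraries. With offsets from transcript lengths, 4503 were higher and 3093 lower, and the median over all genes was 0.135 in place of 0.0758. Without the line block 4222 genes passed. Within the G12S lines 8177 passed, and 12497 without the 4 libraries, and within the G12D lines 365 and 4495.

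The control ASO was compared with no ASO to measure what a non-targeting oligonucleotide changed. At 4 and 24 h 0 genes passed edgeR's quasi-likelihood test, with 482 and 471 at an unadjusted p under 0.05; DESeq2 called 1 and 3 genes and limma-voom 0 and 0. Without the 4 libraries 0 passed at either time, with 1206 and 868 at an unadjusted p under 0.05. At 0 h 3 genes passed, all higher with control ASO, of 4322 at an unadjusted p under 0.05 (DESeq2 585, limma-voom 0). They were LINC02242 (2.97 log2 units) and 2 loci listed only by clone names, all singled out after their values were seen, and without the 4 libraries 0 genes passed, with 684 at an unadjusted p under 0.05. Of the members of the 28 lists 0 passed at any of the 3 times. NRAS stood at -0.30 (adjusted p = 0.667) at 0 h, -0.07 at 4 h and 0.03 at 24 h, and MYC at -0.24, -0.37 and 0.08. Camera placed mitochondrial transcripts, G2/M genes and heat shock genes lower at 0 h with the preset correlation, and each call was lost with an estimated correlation (adjusted p = 0.867, 0.920 and 0.920).

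Gilteritinib changed many genes in the resistant lines without ASO. There was no vehicle arm over time, so effects of the drug and of time cannot be separated. Of 15 STAT5 and cytokine feedback targets 9 fell and 1 rose at 4 h (10 and 1 adjusted over the list alone), which camera called down (adjusted p = 3.86e-06; adjusted p = 0.0586 with an estimated correlation). Among them the kinase PIM1 fell by 3.02 log2 units (SE 0.27; 86.4 ± 42.4 to 10.9 ± 3.68 CPM, n = 8) and CISH by 2.12. The heat shock genes HSPA6 (-3.10), HSPA1B (-2.78) and HSPA1A (-2.53), the chemokine CXCL8 (-2.33) and the enolase ENO2 (-2.21) fell too. Interferon genes rose, OAS2 by 2.00 (SE 0.24), IFI44 by 1.96, OASL by 1.74, RSAD2 by 1.67 and OAS1 by 1.66, and so did HMOX1 by 1.70. DUSP6 fell by 0.83 (adjusted p = 0.0104), SPRY4 by 1.14 (adjusted p = 0.0108) and MYC by 0.66 (adjusted p = 0.0171), while FLT3 stood at -0.26 (adjusted p = 0.242) and NRAS at 0.10 (adjusted p = 0.868). Of 27 interferon genes 17 rose (18 adjusted over the list alone). Of 21 p53 targets 14 rose (15 higher and 1 lower adjusted over the list alone), among them PHLDA3 (1.48) and MDM2 (0.88). Of 21 cholesterol genes 17 fell (18 adjusted over the list alone), among them INSIG1 (-1.81). These 3 held with an estimated correlation (adjusted p = 0.0460, 0.0448 and 0.0448). Of 16 RAS/MAPK genes 11 fell (12 lower and 1 higher adjusted over the list alone; PLAUR at -1.52, CCND1 at -1.87). Of 21 immediate-early genes 12 fell (12 adjusted over the list alone; EGR1 at -1.61), and of 25 G2/M genes 12 rose (15 adjusted over the list alone; BIRC5 at 0.67). The 3 calls were lost, with adjusted p = 0.176, 0.195 and 0.475 with an estimated correlation. In the BCL2 family MCL1 (-0.59), BCL2A1 (-1.06) and BCL2L11 (-0.51) fell and BAX (0.32) and BMF (0.90) rose.

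At 24 h without ASO PIM1 (-3.76) and CISH (-2.04) were still lower, with CYP26B1 (-4.10), CXCL10 (-3.63), INHBA (-3.01), EGR3 (-2.95) and ADGRG3 (-2.94). ARRDC3 (2.13), GDF7 (2.06), SIRPB2 (1.97), C22orf15 (1.90), IFI6 (1.85) and PLD4 (1.74) rose. SPRY4 fell by 2.02 (adjusted p = 7.96e-06) and CD14 by 1.19 (adjusted p = 0.000172), and FLT3 rose by 0.57 (adjusted p = 0.00237) and HRAS by 0.66 (adjusted p = 1.90e-05). MYC stood at 0.09 (adjusted p = 0.799), DUSP6 at -0.14 (adjusted p = 0.709) and MPO at -0.30 (adjusted p = 0.0902). Of 21 NF-kB genes 14 fell and 1 rose (RELB at -2.14, ICAM1 at -1.47), of 21 cholesterol genes 19 fell (CYP51A1 at -1.18), of 22 ATF4 genes 16 fell and 1 rose (CHAC1 at -2.82, DDIT3 at -1.50) and of 9 lymphoid markers 5 fell (TRAC at -2.05), with adjusted p = 0.0384, 0.0384, 0.0494 and 0.0384 with an estimated correlation. Adjusted over the list alone 15, 20, 19 and 5 fell. Of 33 monocyte markers 8 rose and 4 fell, LILRB2 by 1.78 and the lysozyme gene LYZ by 1.22, of 25 lysosome genes 13 rose and 1 fell (adjusted p = 0.284 with an estimated correlation), and of MYC and ribosome biogenesis 4 of 25 rose.

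By edgeR's quasi-likelihood test 6752 genes passed at 4 h without ASO (3495 higher, 3257 lower) and 9348 at 24 h (5218 higher, 4130 lower), and 9886 and 12756 without the 4 libraries. With control ASO 8360 (4250 higher, 4110 lower) and 12735 (6617 higher, 6118 lower) passed, and 8165 and 12079 without them. Fits to only the groups compared, which keep the shallow libraries, called 829 and 2534 genes with control ASO and 10245 at 4 h without ASO. PIM1 was lower in that arm too, at -2.79 at 4 h and -3.72 at 24 h, and OAS2 (1.84) and HMOX1 (2.09) rose at 4 h. CA9, a hypoxia gene, was at -5.32 and TSPAN7 at 5.07 at 24 h with control ASO. The reference group of both values holds the shallow libraries, and how far these libraries set the values is not shown here. Neither gene is among the changes named at 24 h without ASO or with NRAS ASO. MYC stood at -0.80 at 4 h (adjusted p = 0.00342) and 0.40 at 24 h (adjusted p = 0.122). All 13 mitochondrial transcripts rose at 24 h with control ASO (adjusted p = 0.369 with an estimated correlation), 9 of them without the 4 libraries.

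In the NRAS ASO arm, too, drug and time cannot be separated. At 4 h of gilteritinib PIM1 (-3.42), GPR84 (-2.55), CISH (-2.36), CCND1 (-2.22), TNF (-2.11) and the glucose transporter SLC2A3 (-2.09) were lower than at 0 h. IFI44 (1.98), OASL (1.78), HCG27 (1.76), HMOX1 (1.73), OAS2 (1.73) and MIR34AHG (1.47) were higher. MYC fell by 1.66 (adjusted p = 2.03e-08) and SPRY4 by 1.83 (adjusted p = 6.28e-05). At 24 h INHBA (-4.56), PIM1 (-4.19), GPR84 (-3.81), CHAC1 (-3.69), TNF (-3.27) and the aldolase ALDOC (-3.19) fell most. BTBD6P1 (3.03), ARRDC3 (2.90), SYNPO (2.59), PRUNE2 (2.55), EPAS1 (2.52) and DPEP2 (2.37) rose most. MYC was lower by 1.24 (SE 0.22, adjusted p = 3.05e-06), SPRY4 by 2.81 (adjusted p = 1.03e-08), CD14 by 2.01 (adjusted p = 4.74e-08) and MPO by 0.90 (adjusted p = 2.12e-07). Of 25 S phase genes 25 fell at 24 h, of 25 G2/M genes 24 and of MYC and ribosome biogenesis 23, with CDC6 at -1.78, AURKA at -1.38 and RRP12 at -1.03. Adjusted over the list alone, 25, 25 and 23 fell (adjusted p = 0.136 each with an estimated correlation). Of 22 ATF4 genes 20 fell and 1 rose (TRIB3 at -2.92) and of 21 cholesterol genes 20 fell (DHCR7 at -1.88), which held with an estimated correlation (adjusted p = 0.0131 and 0.0425). Monocyte markers went both ways, 14 higher and 5 lower of 33, LILRB2 at 1.67 and CSF1R at 0.96 among the higher. In this arm 7935 genes passed at 4 h (4074 higher, 3861 lower) and 12351 at 24 h (6614 higher, 5737 lower), and 10987 and 15082 without the 4 libraries.

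The interaction asked whether the change from 0 h differed between NRAS ASO and control ASO. At 24 h the change in MYC was lower by 1.65 log2 units with NRAS ASO than with control ASO (SE 0.31, adjusted p = 9.10e-05). The change in CD14 was lower by 1.17 (SE 0.39, adjusted p = 0.0229) and that in MPO by 0.75 (SE 0.20, adjusted p = 0.00396). The control ASO side at 0 h holds the shallow libraries. MYC there was at 302 ± 93.3 CPM, against 351 ± 43.1 without ASO. CD14 was low, at 0.797 ± 0.417 CPM with control ASO at 0 h and 0.149 ± 0.117 with NRAS ASO at 24 h. For MPO the difference between the ASO arms passed the threshold at neither 0 nor 24 h. The widest differences below 0 were DDN (-2.04), GPR84 (-2.00), PRR7 (-1.98), the cytokine MIF (-1.87), INHBA (-1.81) and the neuropeptide GAL (-1.80), and those above 0 LINC01551 (2.30; 0.62 and adjusted p = 0.124 without the 4 libraries), PNPLA7 (2.04), BMF (1.81), SH3TC1 (1.74), the cannabinoid receptor CNR2 (1.55) and BTBD6P1 (1.54). SPRY4 stood at -1.10 (adjusted p = 0.108), FLT3 at -0.43 (adjusted p = 0.136) and NRAS at -0.47 (adjusted p = 0.476). All 25 genes of MYC and ribosome biogenesis, of S phase and of G2/M were lower, with NCL at -1.03, PCNA at -1.20 and CCNA2 at -1.32, in 8 of 8 lines by list mean (exact sign-flip p = 0.00781, adjusted p = 0.0273; adjusted p = 0.117, 0.181 and 0.182 with an estimated correlation in camera). Of 18 unfolded protein response genes 13 were lower (XBP1 at -1.24), of 22 ATF4 genes 14 lower and 1 higher (PSAT1 at -1.52) and of 14 heat shock genes 9 lower (HSPA8 at -1.61), with adjusted p = 0.182, 0.182 and 0.280 with an estimated correlation. Adjusted over the list alone 15, 16 and 9 were lower. RAS/MAPK output had 5 of 16 lower and 2 higher (6 and 2 adjusted over the list alone), which camera did not call (adjusted p = 0.0807).

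At 24 h 6977 genes differed in their response (3106 higher, 3871 lower) by edgeR's quasi-likelihood test, and 7588 without the 4 libraries. A fit to only the groups compared called 1697 (436 higher, 1261 lower), and within the G12D lines 121 passed, or 1361 without the 4 libraries. The split was 3538 higher and 2665 lower with length offsets and 2216 and 4317 with limma-voom. At 4 h 0 genes passed, with 3284 at an unadjusted p under 0.05, 12 by DESeq2 and 0 by limma-voom; 7 passed without the 4 libraries. There MYC stood at -0.85 (adjusted p = 0.416) and 7 of 25 genes of MYC and ribosome biogenesis were lower when adjusted over the list alone, 0 over all genes (adjusted p = 0.426 with an estimated correlation).

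**Figure D3:**
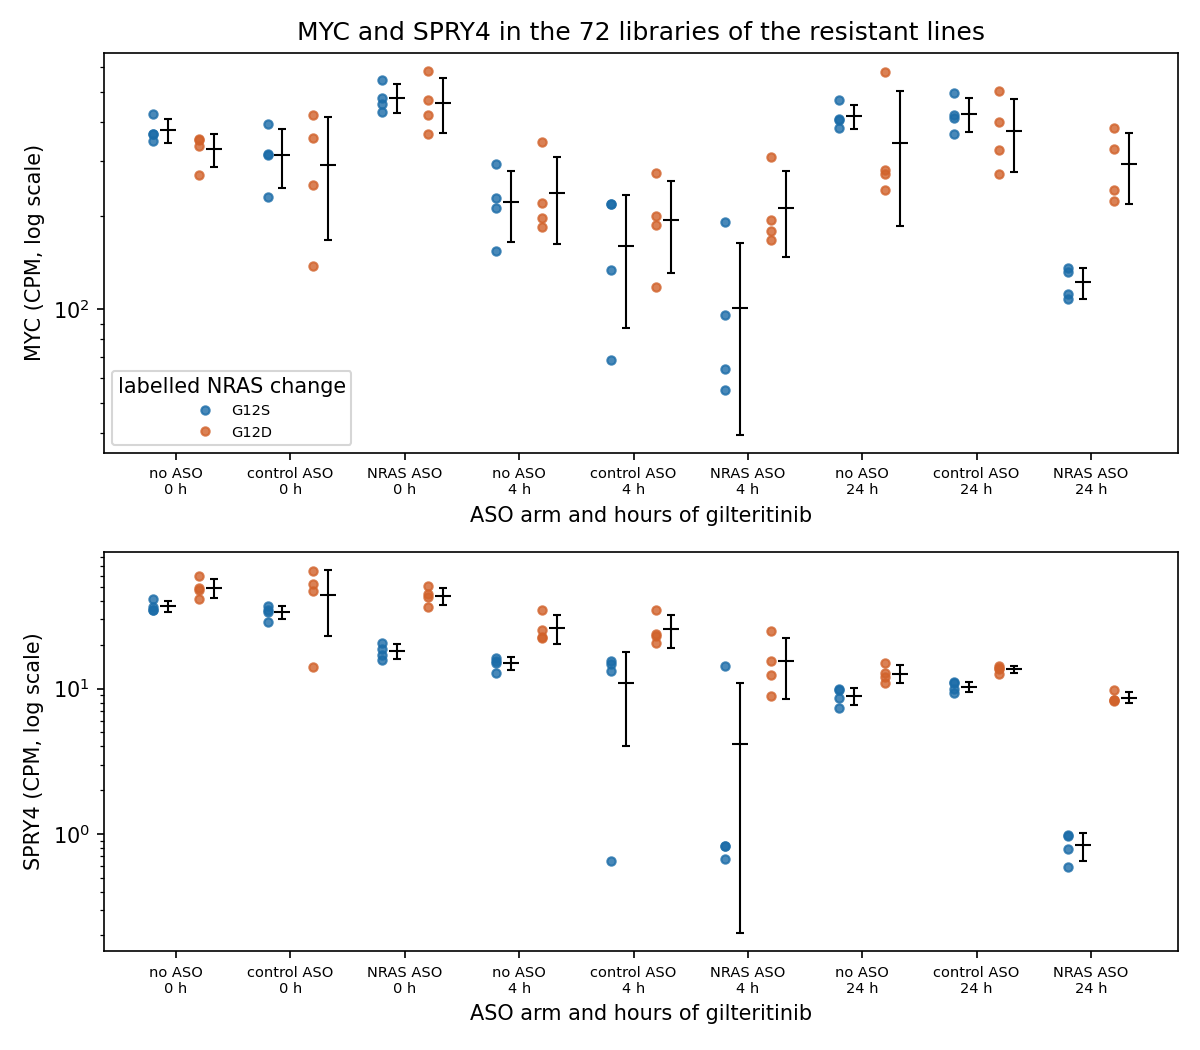
MYC and SPRY4 in CPM on a log axis, 1 point per library, by ASO arm and hours of gilteritinib. Bars give the mean and SD over the 4 lines of each genotype, and colours mark NRAS G12S and G12D lines. At 24 h with NRAS ASO MYC lay at 122 ± 14 CPM in G12S and 293 ± 75.2 CPM in G12D lines.

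The lines labelled G12S and G12D were compared for the effect of the NRAS ASO. At 24 h MYC changed by -1.80 ± 0.10 log2 units in G12S and -0.35 ± 0.16 in G12D lines (mean ± SD, n = 4 each; difference -1.44, SE 0.34, adjusted p = 0.00422), and SPRY4 by -3.54 ± 0.26 and -0.65 ± 0.13 (difference -2.98, adjusted p = 0.00648). DUSP6 did not differ detectably, at -0.53 ± 0.08 and -0.50 ± 0.26 (difference -0.01, SE 0.40, adjusted p = 0.999). KIT (difference 2.28), SYNPO (2.22), EPAS1 (2.05), AGXT (2.02), BTBD6P1 (1.83) and PTGDS (1.79) were higher with NRAS ASO by more in G12S lines, and the cyclin CCND1 (-3.17), DDN (-3.15), telomerase (TERT, -2.70), the phosphatase CDC25A (-2.48) and RHEX (-2.40) lower by more. BCL2 changed by -0.99 ± 0.13 in G12S and by 0.00 ± 0.09 in G12D lines (difference -0.99, adjusted p = 0.000880), and BMF by 2.30 ± 0.21 and 0.61 ± 0.27 (difference 1.68, adjusted p = 3.13e-06). The knockdown itself was -2.54 ± 0.15 log2 units in G12S and -0.98 ± 0.22 in G12D lines (difference -1.57, SE 0.57, adjusted p = 0.0986; adjusted p = 2.95e-14 without the 4 libraries), so genotype and depth of the NRAS knockdown went together.

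Of 25 genes of MYC and ribosome biogenesis 20 fell by more in G12S lines (24 adjusted over the list alone; list means -1.35 against -0.31), and of 25 S phase genes 22 did (25 adjusted over the list alone; -1.65 against -0.39), both held with an estimated correlation (adjusted p = 0.000103 each). Examples were NCL (-1.15), MRTO4 (-1.08), CDC6 (-2.02) and E2F1 (-1.91). G2/M had 17 of 25 (23 adjusted over the list alone), cholesterol 8 of 21 (11), RAS/MAPK output 6 of 16 (10; ETV4 at -1.54, ETV5 at -1.94) and ATF4 8 of 22 (11; PHGDH at -1.17), with the count adjusted over the list alone first in each bracket and adjusted p = 0.0603, 0.0603, 0.131 and 0.111 with an estimated correlation. Of 21 immediate-early genes 5 were higher (8 higher and 1 lower adjusted over the list alone; FOS at 0.80; adjusted p = 0.325 with an estimated correlation) and of 21 p53 targets 3 (6 adjusted over the list alone; TP53INP1 at 1.25; adjusted p = 0.111 with an estimated correlation). The exact permutation of 4 against 4 lines gave p = 0.0286, the smallest possible, for these 8 lists (adjusted p = 0.0533). By edgeR's quasi-likelihood test 1731 genes differed at 24 h (575 higher, 1156 lower) and 5009 without the 4 libraries, and 4681 in a fit to only the groups compared. Leaving out 1 line at a time gave between 979 (without 10L) and 2473 (without 12L) genes. At 0 h 2 genes differed, CD93 (-1.50, adjusted p = 0.0101) and MDGA1 (-1.86, adjusted p = 0.0163), the latter named after its value was seen, and 52 without the 4 libraries. Immediate-early genes had 0 of 21 different over all genes and 14 lower in G12S lines when adjusted over the list alone (list means -1.04 against -0.02; adjusted p = 0.0137 with an estimated correlation), with an exact permutation p of 0.0286 (adjusted p = 0.764).

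Without ASO at 0 h MPO and VCAN were lower, and the interferon-induced genes IFIT2 and IFIT3 higher, in G12S than in G12D lines; genotype cannot be separated here from any other difference between the 2 sets of lines. MPO, the granule enzyme myeloperoxidase, was at 28.9 ± 7.62 CPM in G12S and 1300 ± 843 CPM in G12D lines (n = 4 each; -5.50 log2 units, SE 0.46, adjusted p = 0.000137). VCAN (-5.30), SOCS6 (-5.84), ANKRD18A (-5.31) and the repeated locus REXO1L1P (-4.94) were lower in G12S lines too, and FBN2 had between 0 and 1 reads in the 4 G12S libraries against 362 to 1793 in the G12D ones. ADGRL3 (3.88), the clock gene PER3 (3.46), MEST (3.30), IFIT2 (3.30), SLC22A23 (3.08) and IFIT3 (2.98) were higher in G12S lines. DUSP6 was lower in G12S lines by 0.99 (adjusted p = 0.00923) and SPRY4 by 0.44 (adjusted p = 0.0232), and FLT3 was higher by 0.77 (adjusted p = 0.0227). NRAS stood at 0.22 (adjusted p = 0.293) and MYC at 0.19 (adjusted p = 0.218). Of 21 cholesterol genes 17 were higher (21 adjusted over the list alone; INSIG1 at 1.55), of 27 interferon genes 14 higher and 1 lower (ISG15 at 2.03, IFITM1 at -2.75) and of 22 ATF4 genes 14 higher and 1 lower (ASNS at 1.03, SLC7A11 at -1.27), each lost with an estimated correlation (adjusted p = 0.645 each). Of granule genes 4 of 16 were lower (CTSG at -2.01, MS4A3 at -3.43; adjusted p = 0.730 with an estimated correlation) and of MHC class II genes 4 of 11 higher (CD74 at 1.17). By edgeR's quasi-likelihood test 4562 of 25573 genes differed, 2437 higher and 2125 lower in G12S lines, and between 2939 (without 5L) and 4673 (without 9L) when 1 line was left out.

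MOLM14 gave 1 library per time, so its values have no replicate error. The resistant cultures had been kept in gilteritinib, and whether it was withdrawn before 0 h is not given. An effect of that history on the 0 h differences from MOLM14 cannot be separated. At 0 h it held MYC at 518 CPM, SPRY4 at 10.8, DUSP6 at 56.5, MPO at 32.2 and FLT3 at 220 CPM. The 8 resistant lines without ASO held 353 ± 41.1, 43.3 ± 8.60, 95.1 ± 42.2, 671 ± 879 and 245 ± 83.3 CPM in the same order. These means, and the list medians below, pool the genotypes. Scaled without MOLM14, DUSP6 was at 63.7 ± 5.38 CPM in G12S and 125 ± 39.3 in G12D lines, and MPO at 28.9 ± 7.62 and 1300 ± 843. SPRY4 was at 36.8 ± 3.03 and 49.3 ± 7.45 CPM, above MOLM14 in both. After 4 h of gilteritinib MYC stood at 24.0 CPM, SPRY4 at 0.233 and DUSP6 at 6.20 in MOLM14, and after 24 h at 41.4, 0.722 and 14 CPM, while FLT3 reached 474 and NRAS 59.5 CPM. At 0 h the median of parental minus resistant values lay at -0.64 for RAS/MAPK output, -1.62 for immediate-early genes, -1.08 for cholesterol genes, -0.84 for granule genes, -0.69 for interferon genes, -0.62 for glycolysis and hypoxia, -0.53 for ATF4 and -0.51 for NF-kB genes (percentile 0.0 of matched random lists each). It lay at 1.25 for MHC class II, 0.61 for p53 targets, 0.50 for MYC and ribosome biogenesis, 0.42 for heat shock genes and 0.24 for mitochondrial transcripts, a sign of RNA quality (percentile 100.0 each). Over 24 h of drug the list median in MOLM14 changed by -2.52 for MYC and ribosome biogenesis and for heat shock genes, -2.22 for S phase, -1.90 for G2/M, -1.38 for RAS/MAPK output and for the unfolded protein response, -1.37 for granule genes, -1.34 for STAT5 targets and -1.14 for ATF4 genes (percentile 0.0 each). It changed by 0.89 for MHC class II, 0.82 for immediate-early genes, 0.54 for interferon genes and 0.41 for lysosome genes (percentile 100.0 each). Mitochondrial transcripts changed by -1.19 (percentile 0.6). Their share of the reads was 1.61% in the 24 h library against 2.76% at 0 h, and the 10 most abundant genes held 11.2% against 8.45%.

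The response of each resistant line was then set beside that of MOLM14, across 32241 genes, which are not independent replicates. At 24 h the parental side was the library with the lower mitochondrial share. The 24 h response with NRAS ASO correlated with the parental one at r = 0.380 ± 0.127 (mean ± SD over 8 lines), against 0.030 ± 0.069 with control ASO, a difference of 0.350 ± 0.151, higher in 8 of 8 lines (exact two-sided sign-flip p = 0.00781, the smallest possible). By Spearman's rho the values were 0.388 and 0.027. Against no ASO, at 0.079, the exact test also gave p = 0.00781. In G12S lines r was 0.474 against 0.034 and in G12D lines 0.286 against 0.026 (exact p = 0.125 each, the smallest that 4 lines allow); the difference between genotypes was not tested. Without 8L and 12L, whose 0 h control libraries were shallow, r was 0.352 against 0.049 (exact p = 0.0312, the smallest for 6 lines). At 4 h r was 0.275 ± 0.105 with NRAS ASO and 0.160 ± 0.082 with control ASO, higher in 6 of 8 lines (exact p = 0.0547). Against no ASO, at 0.151 ± 0.086, it was higher in 8 of 8 lines (exact p = 0.00781). Both ASO arms at 4 h hold a 5L library whose NRAS went against its label. Without 5L, 8L and 12L r was 0.263 with NRAS ASO and 0.178 with control ASO (higher in 4 of 5 lines, exact p = 0.188, where 0.0625 is the smallest possible), and without 8L and 12L 0.239 and 0.178 (exact p = 0.219). The NRAS ASO effect at 0 h correlated at 0.071 ± 0.076 with the parental-minus-resistant difference (above 0 in 8 of 8 lines, exact p = 0.00781; Spearman 0.093) and at 0.064 ± 0.051 with the 24 h gilteritinib effect without ASO (Spearman 0.081). No library entered both sides of these correlations. Benjamini-Hochberg adjusted over the 4 relations with all 8 lines and control ASO as the reference of the NRAS ASO, the exact p was 0.0547 for the 4 h response and 0.0104 for each of the others.

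**Figure D4:**
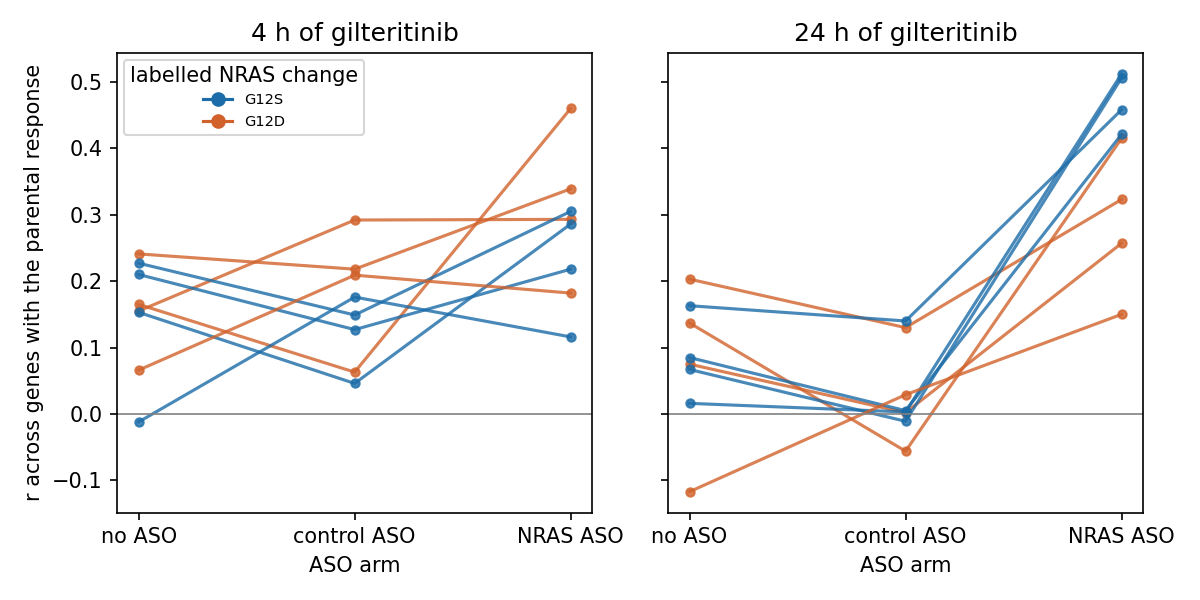
Correlation r across 32241 genes of each line's gilteritinib response with that of MOLM14 at 4 h and at 24 h, 1 point per line and ASO arm, coloured by genotype. At 24 h the mean was 0.380 with NRAS ASO and 0.030 with control ASO.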

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

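The tests of the 5L pair, of the shallow libraries and of the larger effect in G12S lines were chosen only after the results were seen, while the counts over other splits of the samples were planned before. Among 99 groups of 8 values examined, 19 values lay far from the others of their group. For independent, normally distributed values chance gives such a value in about 1 in 20 groups. That rate does not apply here, because the groups hold the same 8 lines and mix G12S with G12D lines. The same line and gene therefore recur among the 19.

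In the pair of 5L at 4 h, NRAS stood at 133 CPM in the library labelled NRAS ASO, against 20.7 to 71.6 CPM in the other 7 lines. Over 2300 genes called without the pair and the shallow libraries, NRAS left out, the 5L difference correlated with the change in that fit at r = -0.78, and the other lines, which entered it, at 0.70 to 0.90. Neither library deviated from its group most like another line (0 of the pair), which argues against a library of another line. An exchange of the labels of this pair is therefore a candidate explanation that the values fit, and no biological explanation was tested.

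In the shallow control ASO libraries of 8L and 12L at 0 h the 10 most abundant genes held 16.4% and 16.6% of the reads. The other 6 control ASO libraries at 0 h, thinned to the lower total, reached at most 8.7%. Thinning of finished counts leaves each gene's expected share unchanged, so this outcome was largely set in advance. It shows that drawing fewer reads does not by itself raise the share, and it cannot test how a shallow library arose. The rank correlation of the control ASO difference from no ASO with transcript length was 0.10 in the shallow libraries and -0.02 to 0.05 in the other lines, so a length bias could contribute. No biological explanation was tested.

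The NRAS ASO effect at 24 h was larger in lines labelled G12S, where 1731 genes differed, SPRY4 by -2.98 and MYC by -1.44. Without the shallow libraries and the 5L pair 5009 genes differed. None of these libraries is at 24 h, so leaving them out acts only through the spread and line block of the shared fit. The count therefore cannot test them as the cause. The shallowest G12S knockdown was -2.37 log2 units and the deepest G12D knockdown -1.31, a gap of 1.06, so the ranges did not overlap. The genotype and a deeper knockdown of NRAS therefore cannot be told apart, and either may lie behind the difference.

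The effects that differed between the genotypes at 24 h included KIT (2.28), SYNPO (2.22), EPAS1 (2.05), AGXT (2.02), BTBD6P1 (1.83) and PTGDS (1.79) above 0, and CCND1 (-3.17), DDN (-3.15), TERT (-2.70), CDC25A (-2.48) and RHEX (-2.40) below 0. At 0 h 2 genes differed, among them CD93 (-1.50). The response to gilteritinib at 24 h differed between NRAS ASO and control ASO in 6977 genes. Of these MYC (-1.65), CD14 (-1.17), MPO (-0.75), DDN (-2.04), GPR84 (-2.00), PRR7 (-1.98), MIF (-1.87), INHBA (-1.81) and GAL (-1.80) were lower with NRAS ASO, and LINC01551 (2.30), PNPLA7 (2.04), BMF (1.81), SH3TC1 (1.74), CNR2 (1.55) and BTBD6P1 (1.54) were higher. The control ASO side of these differences includes the shallow libraries at 0 h.

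Single libraries stood apart from the other 7 of their group. In 9L MPO was at 2840 CPM with control ASO at 0 h, 2220 at 4 h and 2660 at 24 h, at 2930 and 2260 with NRAS ASO at 4 and 24 h, and at 2700 without ASO at 24 h, where no other line exceeded 1150. DUSP6 in 9L at 24 h was at 106 CPM with NRAS ASO, 121 with control ASO and 137 without ASO, against at most 55.7, 90.8 and 85.2. CD14 in 12L was at 1.85 CPM without ASO at 0 h, 2.40 at 4 h, 1.95 and 1.46 with control ASO at 4 and 24 h and 0.413 with NRAS ASO at 24 h, where the other lines reached 0.83, 1.18, 0.982, 0.537 and 0.179. NRAS in 8L without ASO at 24 h was at 163 CPM (others 89.7 to 116), and HRAS in 12L with NRAS ASO at 0 h at 12.3 CPM (others 7.36 to 8.92). The 10 most abundant genes held 8.40% of the reads of 12L with NRAS ASO at 0 h (others 6.50% to 6.87%) and 8.50% of 5L without ASO at 4 h (others 6.82% to 7.22%).

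Exchanging the group labels within lines gave 128 possible splits, of which 24 were drawn. For NRAS ASO against control ASO at 0 h 1 of 24 splits, the real one, gave as many as 1565 genes (highest other 538). The same held at 24 h (7823, highest other 5259). A share of 1 of 24 is the smallest these splits allow. It was not adjusted over the comparisons, so here and below it argues against chance without excluding it. At 4 h 2 of 24 splits gave at least 68 genes, and chance could not be excluded. The highest, at 200 genes, exchanged the labels of 5L, 9L and 10L, and so put the 5L pair the other way round. It called several times the real count, which points to a structure of the samples. For control ASO against no ASO at 0 h chance could not be excluded, with 3 genes and 4 of 24 splits (highest other 4). At 4 and 24 h 0 genes were called, so that any of the 24 splits gives as many (24 of 24; highest other 0 and 1), and the splits say nothing about chance there. By edgeR's quasi-likelihood test 482 and 471 genes had an unadjusted p under 0.05 at 4 and 24 h, and DESeq2 called 1 and 3.

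For gilteritinib only the real split, 1 of 24, gave as many genes in each arm and at each time. The real counts and highest others were 6752 and 3705 at 4 h and 9348 and 5485 at 24 h without ASO, 8360 and 6126, and 12735 and 8799 with control ASO, and 7935 and 4091, and 12351 and 9348 with NRAS ASO. For the interaction only the real split gave as many genes at 24 h (6977, highest other 4026). At 4 h, with 0 genes called (highest other 0; 3284 at an unadjusted p under 0.05, DESeq2 12), the splits say nothing about chance either. All 35 splits of the 8 lines into 4 and 4 were run for the genotypes. For the difference in the NRAS ASO effect at 24 h only the real split gave as many genes (1731, highest other 0). The same held for untreated lines (4562, highest other 1). At 1 of 35 splits each, the smallest share possible, this argues against chance without excluding it. At 0 h 16 of 35 splits gave at least 2 genes, so that count does not argue against chance. There the split of 5L, 8L, 10L and 12L from the other lines gave 1066, many times the real count, and it sets both lines with a shallow control ASO library on 1 side, which points to a structure of the samples.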

How the results depend on the processing

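Several alternatives were chosen only after the data had been seen. They left out the 5L pair at 4 h, alone or with the shallow libraries. They also compared arms within a genotype, with all libraries or without both kinds. Others used no ASO as the reference without these libraries or without the block, and similarity without 8L and 12L or without 5L, 8L and 12L. Of 4170 values of named genes under 10 alternatives, 3917 kept their side of the threshold, with 53 values past it under neither setting and of another sign. Of the others, 179 were no longer past it, 72 were newly past it and 2 had the opposite sign. The cause was not tested for the counts and values below, except that fits to the groups compared use fewer libraries. Comparisons within a genotype come from the fit to all lines, so their spread is shared with the lines of the other genotype.

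The libraries carry the line as a pairing, and without the replicate block the counts of genes were 901 at 0 h, 0 at 4 h and 4222 at 24 h for NRAS ASO against control ASO, and 27 for control ASO against no ASO at 0 h. They were 3534 and 5869 for gilteritinib at 4 and 24 h without ASO, 4530 at 4 h with NRAS ASO, 4380 for the interaction at 24 h, and 0 and 653 for the genotype difference of the NRAS ASO effect at 0 and 24 h. For NRAS ASO against no ASO they were 0 at 0 h, 0 at 4 h and 3249 at 24 h, against 221, 83 and 6538 with the block. The other counts of the main comparisons stayed within 1.5 times of those with the block, and 91 values of named genes were no longer past the threshold without it.

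For NRAS ASO against control ASO at 0 h, 765 genes passed with no filter on low counts, 4282 with DESeq2, 680 without the shallow libraries, 839 without these and the 5L pair, 221 against no ASO (735 without both kinds), 2 with only the groups compared and 2 within the G12D lines (95 without both kinds). At 4 h the counts were 240 with DESeq2, 42 with length offsets, 585 without the shallow libraries, 794 without the 5L pair, 2303 without both and 0 with only the groups compared. Within the G12S lines, which include the 5L pair, 0 genes passed (1668 at an unadjusted p under 0.05), and 3717 without both kinds of library. Within the G12D lines 24 passed, and 621 without both. Against no ASO 83 passed at 4 h, and 2346 without both. At 24 h they were 11923 without the shallow libraries, 12021 without these and the 5L pair, and 365 within the G12D lines. Without both kinds 4495 passed within the G12D and 12497 within the G12S lines. For control ASO against no ASO at 0 h, DESeq2 gave 585, limma-voom 0, leaving out the shallow libraries 0, leaving out both kinds 0, only the groups compared 0 and the G12D lines 1; without both kinds each genotype gave 0. At 4 h DESeq2 and the G12S lines gave 1 each, the G12S lines without both kinds 4, and at 24 h DESeq2 gave 3 and only the groups compared 1. For gilteritinib without ASO, 10245 genes passed at 4 h with only the groups compared, and 3734 and 5811 at 4 and 24 h within the G12D lines (7578 and 9970 without both kinds). With control ASO only the groups compared gave 829 and 2534, the G12S lines 4861 and 7634 (6373 and 10336 without both kinds) and the G12D lines 4897 and 8460 (7032 and 9094). With NRAS ASO the G12S lines gave 5074 at 4 h (8752 without both kinds) and the G12D lines 5252 and 7257 (9497 and 11381). The interaction at 4 h had 12 genes with DESeq2, 2 without the 5L pair, 7 without both kinds of library and 6 within the G12S lines (834 without both kinds), and at 24 h it had 1697 with only the groups compared and 121 within the G12D lines (1361 without both kinds). The genotype difference at 0 h had 24 genes with DESeq2, 1 with length offsets, 0 with only the groups compared, 47 without the 5L pair and 52 without both. At 24 h it had 2670 with DESeq2, 4632 without the shallow libraries, 4681 with only the groups compared and 5009 without both. Leaving out 1 line at a time gave 0 to 64 genes for the genotype difference at 0 h, 979 to 2473 at 24 h and 2939 to 4673 for untreated G12S against G12D lines. By Spearman correlation the similarity difference at 4 h was 0.134 (exact p = 0.0391). Over genes with a mean CPM of at least 10, r at 24 h with NRAS ASO was 0.575 in place of 0.380, its difference from control ASO 0.547 in place of 0.350, and the difference at 4 h 0.197 in place of 0.115 (exact p = 0.0547). The NRAS ASO effect then correlated with the parental-minus-resistant difference at 0.187 in place of 0.071 and with the gilteritinib effect at 0.157 in place of 0.064, each above 0 in 7 of 8 lines (exact p = 0.0156). The mean NRAS ASO profile correlated with the gilteritinib effect at 0.210 in place of 0.148. Of 476 list tests 197 passed with the preset and 17 with an estimated correlation. The 2 values with the opposite sign were of FLT3 at 4 h of gilteritinib with control ASO, at -0.20 without the shallow libraries and -0.23 without both kinds. The libraries of 2.33 and 2.79 M reads were both in the control ASO group at 0 h, and what their depth limits was not tested apart from their composition.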

Other observations

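The mean change of the 27 interferon genes at 4 h of gilteritinib was set out by genotype. Without ASO it was 1.31 ± 0.14 log2 units in G12S and 0.31 ± 0.18 in G12D lines (SD, n = 4 each), with control ASO 1.25 ± 0.56 and 0.49 ± 0.26, and with NRAS ASO 1.05 ± 0.36 and 0.26 ± 0.12. The difference between genotypes was not tested in any arm, and the comparison was chosen only after these values were seen. At 0 h without ASO IFIT2 and IFIT3, antiviral genes induced by interferon, already stood higher in the G12S lines, at 3.30 and 2.98 log2 units above the G12D lines.

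Within the G12S lines 25 of 25 genes of MYC and ribosome biogenesis, 25 of 25 S phase genes and 25 of 25 G2/M genes fell with NRAS ASO at 24 h, with all libraries and without shallow libraries and the 5L pair at 4 h. In G12D lines 1, 3 and 1 fell with all libraries (5, 14 and 3 adjusted over the list alone), and 18, 20 and 8 without the shallow libraries and the pair, so the count there depends on those libraries. No list was tested within a genotype. With all libraries 5 of 21 p53 targets rose and 2 fell in G12S lines and 0 changed in G12D lines, and of 25 lysosome genes 3 rose and 2 fell in G12S lines and 1 fell in G12D lines. Without the shallow libraries and the pair, of 21 p53 targets 12 rose and 3 fell in G12S lines, and 1 rose and 4 fell in G12D lines. Of 25 lysosome genes 7 rose and 6 fell in G12S lines and 11 fell in G12D lines. For p53 targets the genotype difference with all libraries had adjusted p = 0.111 with an estimated correlation, and for lysosome genes adjusted p = 0.383 with an estimated correlation.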
